A study of Gallus gallus with 16 samples.

How the data were processed

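Gonads of chicken (Gallus gallus) embryos at embryonic day 19 were profiled by SuperSAGE, which sequences 1 short tag next to the 3'-most NlaIII site of a transcript, so that a tag count stands for transcript abundance without a length correction. The labels describe 16 libraries, 1 for each combination of sex, side (left or right gonad) and substance, each from RNA of 10 individuals. The substances were none, sesame oil, methyltestosterone (a synthetic androgen, 30 pg per g body weight) and tributyltin (an organotin, 10 pg tin per g body weight). The labels do not give the vehicle of methyltestosterone or tributyltin. Tags were aligned by the submitters with Novoalign to galGal4, per the submitters' processing notes, and versions were not stated.

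The table used here held 14074 Ensembl genes and 8 value columns, 1 per sex and substance. Left and right libraries had been joined in it in a way that was not stated, so side differences and the sex difference on each side, which had been planned, could not be computed. Values were deposited by the authors as RPM, the tags (reads) of a gene scaled to a fixed total over the listed genes, and a filler of 0.05 in place of no tag was set to 0. With the filler removed, 100% of the values were within 0.01 of a whole tag, and the largest distance was 0.00356, which gave the tag total of each column. The deposited table also held the authors' p-value per gene for 12 pairs of columns, from a test that was not stated. The authors' log2 ratios for 14 pairs of columns equalled the ratio of the deposited values within 0.01, except 5 text cells in another decimal notation, and they were not used further. The gene symbols of 13 genes had been turned into dates and 1744 genes had no symbol, and these genes were named by Ensembl identifier or not named.

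The plan was a count test in edgeR, with limma in its place if the table held normalised values, which it did. Values were transformed as log2(value + 1), and genes with at least 1 RPM in at least 4 columns were tested, 9280 in all. A linear model with sex and substance as additive terms was fitted to the 8 columns with limma 3.58.1 (empirical Bayes with a mean trend) in R 4.3.3. It left 3 residual degrees of freedom per gene and a prior of 7.39. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. Each sex and substance was 1 column, so the p-values measure only the spread between columns around the additive model, and an effect of a substance in 1 sex had no test. For such effects the values are given with exact Poisson 95% intervals, which cover counting error only. A value of 0 was read against a floor of 3 tags of its column. Tags without molecular identifiers are not independent molecules, so these intervals are minimal.

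Gene lists of pathways and cell types had been written before the data were examined, and 22 of them had enough tested members for camera in limma, with a preset inter-gene correlation of 0.01 and again with an estimated one. With an estimated correlation camera uses only the 3 residual degrees of freedom, so that form had little power whatever the correlation. A further list of W-linked genes had 1 tested member and was not tested as a list. Adjusted p-values of lists are over the lists of a comparison. Per comparison the named genes were the 8 largest rises and the 8 largest falls among called genes with the same direction in every matched pair of columns, and up to 4 called members of each list. They also included 13 genes chosen in advance, such as AMH, DMRT1 and CYP19A1. Where fewer than 5 genes were called, the 5 with the smallest p in each direction were named. Within 1 sex, up to 6 genes in each direction with the largest change and at least 50 RPM in a column were named.

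Alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 20 RPM, median-of-ratios scaling, DESeq2 1.42.0 and edgeR 4.0.16 on the recovered tags, thinning of each column to 314810 tags, subsets of columns, and leaving out each column in turn. For the count tools 7 columns were used, because the tags of the untreated female column were not accepted as whole by a check that reads the filler as a value. On simulated tags with the depths of the real columns, a dispersion of 0.0770 and genes of a mean of at least 20 RPM, limma found 98 of 100 genes with a 4-fold sex difference and 100 of 100 with an 8-fold one. Of its 199 calls 1 was false. For tributyltin against oil it found 64 of 100 and 99 of 100, and 24 of 187 calls (12.8%) were false. For methyltestosterone against untreated it found 72 and 100 of 100 with 0 of 172 calls false. On the same simulated tags of 8 columns edgeR found 100 and 100 of 100 by sex, with 6 of 206 calls false. For tributyltin against oil edgeR found 69 and 100 of 100, with 3 of 172 calls false. For methyltestosterone against untreated edgeR found 95 and 100 of 100, with 5 of 200 calls false. The simulation gave every gene the same dispersion, and its columns differed only in depth and in the planted changes. These shares therefore need not hold for the real columns. There the gene PDK4, with a log2 change of 3.22 for tributyltin against oil, beyond 8-fold, did not pass (limma adjusted p = 0.129).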

Results

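The data cover gonads of male and female chicken embryos at embryonic day 19 after no substance, sesame oil, methyltestosterone or tributyltin, as 8 columns of tags scaled to a common total (RPM), 1 per sex and substance. Each sex thus had 4 columns and each substance 2, each column joined pools of 10 individuals, and p-values measure only the spread between columns. The untreated columns held 1953798 tags in males and 2301752 in females, and the methyltestosterone columns 6669049 and 3154653. The oil columns held only 492619 and 314810 tags, and the tributyltin columns 508095 and 388795. In the untreated and methyltestosterone columns 1 tag was 0.150 to 0.512 RPM, and in the oil and tributyltin columns 1.97 to 3.18 RPM, so weakly expressed genes were measured coarsely there. By profile the untreated and methyltestosterone columns formed 1 set and the oil and tributyltin columns another, and sex parted columns as well. Across 3215 genes with a mean of at least 50 RPM, columns of 1 sex within a set correlated at r = 0.844 to 0.911 and columns of both sexes within a set at 0.765 to 0.873. Columns of 1 sex across the sets correlated at 0.674 to 0.787, and those that differed in both at 0.594 to 0.664 (genes are not independent replicates). Oil against untreated, methyltestosterone against oil and tributyltin against methyltestosterone each cross the sets, so substance and set cannot be separated in them. The sex difference is balanced over the sets.

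The sex difference asks which genes part ovary from testis at this age. Several genes of the female pathway were higher in females and several genes of Sertoli cells higher in males, while others of both kinds did not pass. CYP19A1 (ENSGALG00000013294, chromosome 10), the aromatase that makes oestrogen, was at 28.7 to 118 RPM in the 4 female columns and at 0 to 11.1 in males, a log2 difference of 4.77 (SE 0.73, limma adjusted p = 0.00395). RSPO1, an activator of WNT signalling in the ovary, was at 28.7 to 88.9 in females and 1.02 to 8.25 in males (log2 3.50, SE 0.44, limma adjusted p = 0.00171). SOX9 (ENSGALG00000004386, chromosome 18), the Sertoli cell transcription factor, was at 47.2 to 322 in males and 0 to 30.8 in females, a log2 difference of -4.23 (SE 0.52, limma adjusted p = 0.00161). AMH (ENSGALG00000024368, chromosome 28), the hormone that makes Mullerian ducts regress, was at 6912 to 10834 in males. In females it was at 977 to 1486 except after methyltestosterone, where it was 6774, and its log2 difference was -2.25 (SE 0.34, limma adjusted p = 0.00342).

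Of 15 tested members of the testis and Sertoli list, 6 were lower in females (AMH, SOX9, CLDN11, HEMGN, INHBB and NR5A1) and 1 was higher (SOX10, better known as a neural crest factor). Adjusted over the list alone, 8 were lower and 4 higher. Of 13 members of the ovary and granulosa list 3 were higher in females (CYP19A1, RSPO1 and BMP7) and none lower, or 4 adjusted over the list alone. The camera adjusted p was 0.0108 for the testis list and 0.0319 for the ovary list, and 0.211 for each as an adjusted p with an estimated correlation. DMRT1, the Z-linked testis determinant, did not pass. It was at 4.06 to 66.0 in males and 0 to 31.1 in females, with a log2 difference of -1.71 (SE 0.71, limma adjusted p = 0.222). FOXL2, a granulosa factor, did not pass either, at 126 and 117 in untreated and methyltestosterone females but at 0 and 3.18 (1 tag) after tributyltin and oil (limma adjusted p = 0.134).

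**Figure D1:**
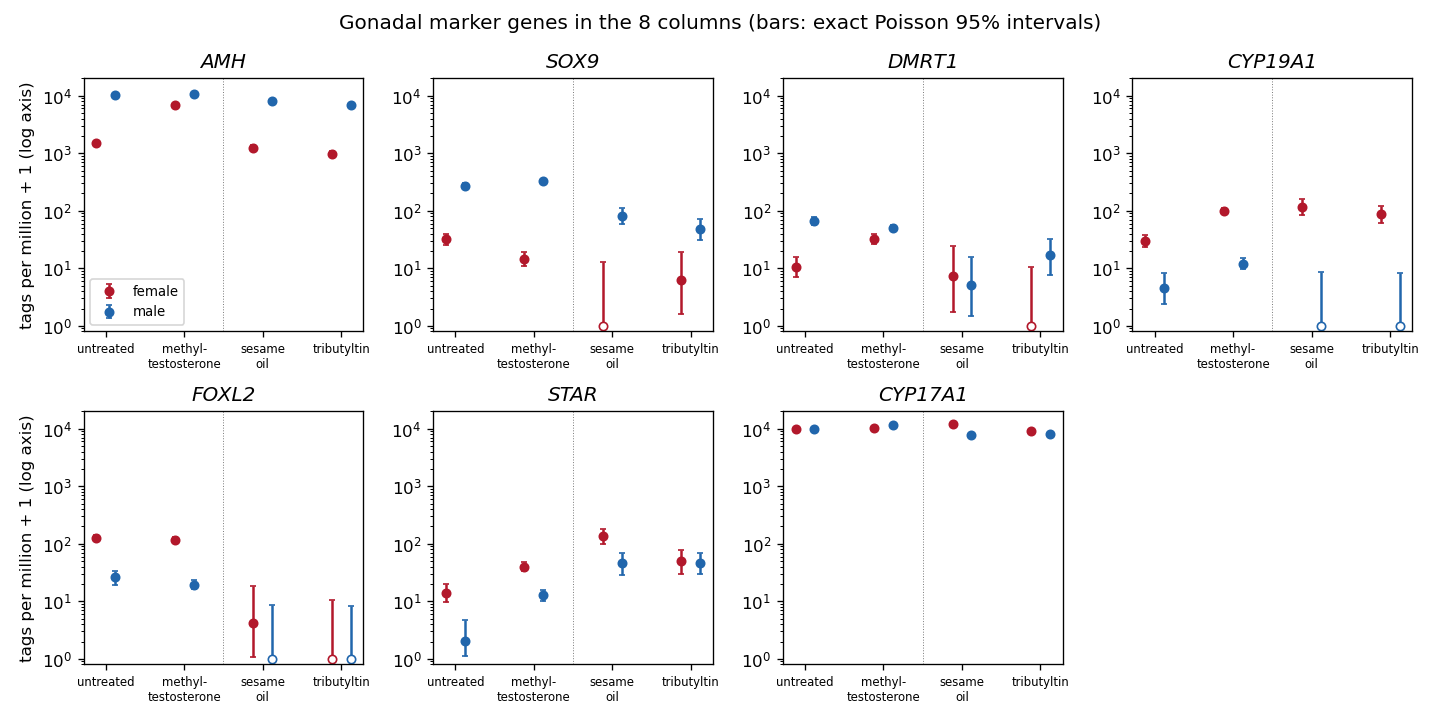
RPM plus 1 on a log axis for 7 gonadal genes in each column, with females in red, males in blue and bars for exact Poisson 95% intervals. Open points have no tag, and the dotted line parts the untreated and methyltestosterone columns from the oil and tributyltin columns. AMH was higher in males for every substance, and the methyltestosterone female value of 6774 lay above the other female values of 977 to 1486.

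Steroid and lipid genes differed gene by gene. Of 20 steroidogenesis genes, CYP19A1 and the luteinising hormone receptor LHCGR were higher in females and HSD3B2 and NR5A1 lower (adjusted over the list alone, 5 higher and 3 lower), and the list had a camera adjusted p of 0.588. CYP17A1, the enzyme that makes androgen precursors, was at 7917 to 12122 in all columns with a log2 difference of 0.15 (SE 0.23). Of 19 PPAR gamma and RXR lipid targets 6 were higher in females, among them the fatty acid binding proteins FABP7 (log2 2.18), FABP3 (1.88) and FABP5, and none lower. Adjusted over the list alone 7 were higher. Its camera adjusted p was 0.00406, and adjusted p = 0.206 with an estimated correlation. In the retinoid list ALDH1A1 (ENSGALG00000015147), a retinaldehyde dehydrogenase on Z, was lower in females by the largest margin of any named gene (log2 -5.27, SE 0.62, limma adjusted p = 0.00125), while STRA6 and DHRS3 were higher. Adjusted over the list alone 3 of its 11 members were higher and 1 lower (camera adjusted p = 0.0460, and adjusted p = 0.211 with an estimated correlation). Other genes much higher in males were COL9A2 (log2 -5.10), the folate receptor FOLR1 (-4.90) and the transporter SLCO4A1 (-4.75). The largest female excesses included BTF3 and HNRPK on unplaced scaffolds (6.04 and 5.94), the oestrogen-responsive GREB1 (4.60), SPINW (4.54) and HHIPL2 (ENSGALG00000009444, chromosome 3; 4.45).

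Markers of other tissues moved with sex as well. Of 13 adrenal markers 9 were higher in females, among them the catecholamine enzymes TH, DBH and PNMT and the granin CHGB (log2 2.51), and NPY was lower. Adjusted over the list alone 11 were higher and 1 lower (camera adjusted p = 3.19e-08, and adjusted p = 0.206 with an estimated correlation). Of 15 mesonephros and kidney markers 4 were higher in females, PCK1 (4.10), CALB1 (4.15), SLC34A1 (3.60) and AQP1 (1.97), and none lower. Adjusted over the list alone 9 were higher and 1 lower (camera adjusted p = 1.16e-05, and adjusted p = 0.206 with an estimated correlation). Red blood cell genes included HBAA, HBAD, HBB and CA2 among 4 higher of 9, and HEMGN, which is also a testis gene in birds, was lower. The same counts held adjusted over the list alone, and the camera adjusted p was 0.00421, with adjusted p = 0.278 with an estimated correlation. In the leukocyte list C1QA, C1QB and CXCL12 were higher (3 of 16, or 6 adjusted over the list alone). In the endothelium list EGFL7 was higher (1 of 13, or 3 adjusted over the list alone). The Mullerian and oviduct genes GAL1 and LTF were higher (2 of 3 tested, also adjusted over the list alone). Camera adjusted p for these last lists was 0.0186, 0.0269 and 0.00421, and adjusted p = 0.211, 0.211 and 0.223 with an estimated correlation. In the untreated female column, markers of gut tissue were also high, as PLA2G2E at 786 and TSPAN8 at 294 RPM, genes named after their values were seen.

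In the matrix list 6 of 30 genes were higher in females, MGP (ENSGALG00000011740, chromosome 1) most (log2 2.94, SE 0.23, limma adjusted p = 0.000203), then COL3A1, COL4A2, ELN, FN1 and COL1A2, while SPARC, LAMA4 and OGN were lower. Adjusted over the list alone 8 were higher and 3 lower, and the camera adjusted p was 0.0269, with adjusted p = 0.455 with an estimated correlation. The germ cell list held 1 lower gene of 15, the stem cell factor receptor KIT, also adjusted over the list alone, with a median of -0.49. No member of the proliferation list passed, over all genes or adjusted over the list alone, and its 25 members had a median of -0.49. Camera adjusted p was 0.0108 and 0.00406 for these, and adjusted p = 0.211 for each with an estimated correlation. The mitochondrial list (1 of 32 lower, COX7C, also adjusted over the list alone) and the ribosomal list (1 of 63 lower, RPL37, or 0 adjusted over the list alone) had medians of -0.24 and -0.32, and both named genes lie on Z. Camera adjusted p was 0.00406 and 3.41e-06, and adjusted p = 0.211 and 0.206 with an estimated correlation. Nuclear receptors (1 higher, RXRG, and NR5A1 and NR5A2 lower, of 19, also adjusted over the list alone), cholesterol synthesis (2 of 15 lower, ACAT2 and PMVK, also adjusted over the list alone, with a median of 0.08 and a mean of -0.14), meiosis (0 of 12, or 3 higher adjusted over the list alone) and muscle (0 of 14, also adjusted over the list alone) were not called as lists. Neither were oxidative stress (TXN and GSTO1 higher, 2 of 19, also adjusted over the list alone) and heat shock (HSPB1 higher, 1 of 27, or 2 higher and 1 lower adjusted over the list alone).

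Birds carry ZZ in males and ZW in females, and Z genes had higher values in males. Over 484 tested Z genes the median log2 difference of females to males was -0.55 (interquartile range -0.99 to 0.02), that is 1.47 times as much in males, against 0.08 over 8479 autosomal genes. The Z median was -0.33 without the filter and -0.37 with a pseudocount of 5. On Z, 53 genes were called higher in males and 12 in females, such as thioredoxin (TXN, log2 1.54). Of 4 tested W genes 3 were higher in females. Tags of W genes summed to 324, 178, 180.0 and 235 RPM in untreated, oil, tributyltin and methyltestosterone females. In males of the same substances they summed to 36.9, 4.06, 0 (95% upper bound 7.26) and 33.9 RPM. Males of the untreated and methyltestosterone columns thus held 11.4% and 14.4% of the female W signal, and oil males 2.28%.

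**Figure D2:**
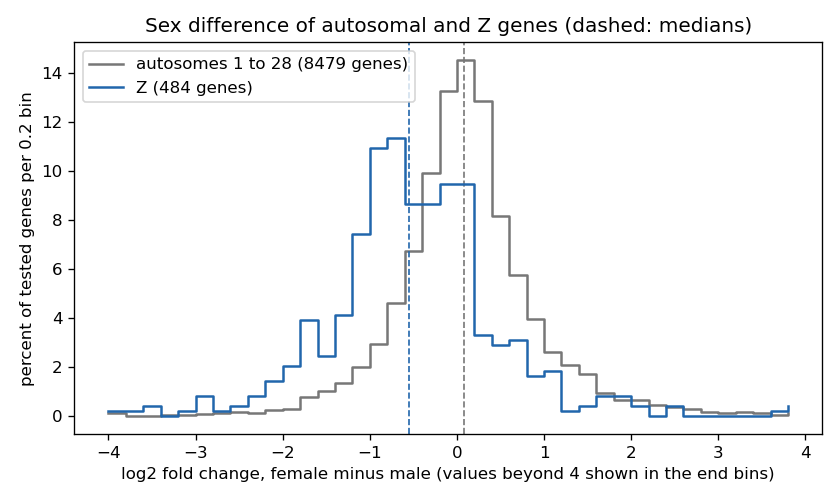
Percent of tested genes by log2 difference of females to males in bins of width 0.2, for autosomal genes in grey and Z genes in blue, with dashed lines at the medians. The Z genes centre at -0.55 and the autosomal genes at 0.08.

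In all, 553 of 9280 genes were called by sex in limma, 341 higher in females and 212 higher in males, and 1717 had an unadjusted p under 0.05. The excess of female-high genes was smaller in limma with median-of-ratios scaling, at 300 higher and 241 lower. On the 7 columns without the untreated female, edgeR gave 288 and 192 with totals alone, 271 and 239 with median-of-ratios factors and 251 and 282 with TMM, so there the direction of the excess depended on the scaling. With the preset correlation 15 of 22 lists were called, and 0 with an estimated one. That second form uses only the 3 residual degrees of freedom, so the loss does not show that correlation within lists explains the calls. For the testis and Sertoli list the estimated correlation was -0.0366, below the preset 0.01. Its unadjusted camera p nevertheless rose from 0.00492 to 0.0575. Within the untreated and methyltestosterone columns alone 1026 genes were called, and within the oil and tributyltin columns alone 27. Without female tributyltin the count was 216, and without male tributyltin 228.

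Tributyltin against oil asks what the organotin, a known ligand of PPAR gamma and RXR, changed against gonads given sesame oil. No gene passed in limma, while 991 of 9280 had an unadjusted p under 0.05 and the smallest adjusted p was 0.129. That gene was PDK4 (ENSGALG00000009700, chromosome 2), a mitochondrial kinase that shifts fuel use to fat and a PPAR target, at 4.06 and 22.2 RPM in oil males and females and 80.7 and 123 after tributyltin (log2 3.22, SE 0.42, higher in both sexes). In the untreated columns PDK4 was at 86.0 and 259. GAL10 (ENSGALG00000016667, chromosome 3), an antimicrobial beta-defensin, was at 28.4 and 1182 after oil and 329 and 3940 after tributyltin (log2 2.61, SE 0.51, limma adjusted p = 0.292). Untreated males and females had GAL10 at 314 and 6816, so for both genes the oil columns were below the untreated ones as well. The other genes of smallest p, none of which passed, were BLOC1S5, CASP8 and C11ORF49 with higher values and C16ORF61, PHLPP2, DLGAP3, MKP3 and TRIP4 with lower values. With edgeR on the tags of 7 columns 5 genes passed, all higher after tributyltin: GAL10, IGFBP7, NFIB, PDK4 and KDM4A, of which KDM4A was named after its values were seen. DESeq2 on these 7 columns called 2 of these, GAL10 and PDK4, as limma did without the untreated female column, and limma on 8 columns restricted to genes with a mean of at least 20 RPM, or with a pseudocount of 5, called PDK4.

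No member of the 22 lists passed over all genes after tributyltin. Of 19 PPAR gamma and RXR lipid targets 1 was higher adjusted over the list alone, and the median of the list was 0.26 (camera adjusted p = 0.464). The lowest adjusted p of a list was 0.139, for the 3 Mullerian and oviduct genes, of which 2 fell adjusted over the list alone (median -1.09). Among the genes chosen in advance, PPARG was at 6.09 and 5.90 RPM in oil and tributyltin males and at 19.1 (6.99 to 41.5) and 0 (upper bound 9.49) in females, where the counting intervals overlap. STAR, which carries cholesterol into mitochondria, was at 133 (96.2 to 180) in oil females and 48.9 (29.4 to 76.3) in tributyltin females, but at 44.7 and 45.3 in males. CYP19A1 was at 118 (82.8 to 162) and 87.5 (60.6 to 122) in females. AMH was at 8167 and 6912 in males and 1242 and 977 in females.

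Within females the largest single-column rises after tributyltin were in ZRSR2 and IGFBP7, then C1S, SNCG1, TAF9 and CNTN1. ZRSR2 had no tag after oil and was at 51.4 (31.4 to 79.4) after tributyltin, 5.40 times the floor of 3 tags before counting error. IGFBP7 was at 3.18 (0.0804 to 17.7, 1 tag) after oil and 165 (127 to 210) after tributyltin. In untreated and methyltestosterone females IGFBP7 was at 123 and 93.2, so the oil column was the one apart. CRIP2, AARS2 and IGFBP4 had no tag after tributyltin and were at 85.8 (56.5 to 125), 60.4 (36.3 to 94.25) and 57.2 (33.9 to 90.4) after oil. These oil values were 11.1, 7.82 and 7.41 times the floor of 3 tags before counting error. Within males NFIB, a transcription factor, was at 112 (84.1 to 145) after oil and 1102 (1013 to 1197) after tributyltin. Females had NFIB at 934 after oil and 1476 after tributyltin, a much smaller difference, and untreated males and females at 96.7 and 138. CD69, PDK4, GAL10, LARP1B and FAM54B were also higher in males, and MSH6, PBX1A and F10 lower. CD69 was at 4.06 in oil and 90.5 in tributyltin males, against 124 in untreated males. The authors' deposited p was under 0.05 for 1781 of 9349 genes in females and for 2144 of 9657 in males. These p-values compare single pools and cannot be set beside the limma count. Leaving out the male oil column raised the limma count from 0 to 49.

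Methyltestosterone against untreated, a comparison added after the data were seen because its 4 columns share a set, gave 32 called genes, 21 higher and 11 lower. A gene of cholesterol synthesis rose and a smooth muscle gene fell, and each stood apart from the oil and tributyltin columns too. FDFT1 (ENSGALG00000016665, chromosome 3), squalene synthase, rose from 44.7 and 66.5 RPM in untreated females and males to 408 and 358 (log2 2.79, SE 0.30, limma adjusted p = 0.0158), and was at 129 to 181 after oil or tributyltin. MYL9, a myosin light chain, fell from 289 and 157 to 54.8 and 41.8 (log2 -2.13, SE 0.29, limma adjusted p = 0.0166), and was at 94.5 to 216 after oil or tributyltin. For other genes the untreated columns were the ones apart. PEX10, a peroxisome gene (log2 4.46), was at 0.869 and 0.512 untreated and 32.5 to 97.7 after any substance. MT-ATP8 of the mitochondrial genome (log2 -3.18) was at 423 and 347 untreated and at 22.2 to 59.3 after any substance. Of 63 ribosomal genes 1 rose and 4 fell, RPL35 (-1.99) and RPL23 (-1.86) among the falls, or 7 rose and 5 fell adjusted over the list alone (median -0.14, mean 0.08, camera adjusted p = 0.103).

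By list, 1 of 15 cholesterol synthesis genes rose after methyltestosterone against untreated (FDFT1, also adjusted over the list alone; camera adjusted p = 0.0148) and 1 of 14 muscle genes fell (MYL9, also adjusted over the list alone; 0.000459). No member passed in the lists of matrix (3 fell adjusted over the list alone), red blood cells (3 rose), kidney (0), adrenal (1 rose and 2 fell) and Mullerian genes (1 rose). Their camera adjusted p was 0.0148, 0.0109, 0.00440, 0.0356 and 0.0165. With an estimated correlation all 7 lost the call, with adjusted p = 0.505 for matrix and adjusted p = 0.458 for the others. The kidney and adrenal lists had lower values after methyltestosterone, and gut markers were high in the untreated female column of the same comparison. Steroid and sex genes did not pass. STAR had a log2 change of 2.08 (SE 0.63), CYP19A1 1.56 (1.04), AMH 1.14 (0.47) and DMRT1 0.59, with limma adjusted p of 0.264 to 0.969.

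Values of females accounted for most of the AMH difference. AMH was at 1486 (1437 to 1537) in untreated and 6774 (6684 to 6866) in methyltestosterone females, against 10186 and 10834 in males. CYP19A1 was at 28.7 (22.2 to 36.5) and 97.3 (86.7 to 109) in females. SOX9 was at 30.8 and 13.6 and FOXL2 at 126 and 117 in the same columns. With either tributyltin column left out, which bears on the spread only, limma called 0 genes in this comparison (898 and 900 with an unadjusted p under 0.05), and without the untreated female column 20. On the same 7 columns, with 1 untreated column, edgeR called 93 and DESeq2 49. With no filter limma on 8 columns called 0 (1131 unadjusted), with a mean of at least 20 RPM 80, and with the 4 columns of these substances alone 1096 (688 higher, 408 lower).

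Methyltestosterone against oil, oil against untreated and tributyltin against methyltestosterone each crossed the sets. Against oil, 744 genes were called after methyltestosterone, 541 higher and 203 lower, while oil against untreated called 590 (257 higher, 333 lower). Tributyltin against methyltestosterone called 965 (294 higher, 671 lower). Counts and the balance of directions depended on the scaling and on single columns. For methyltestosterone against oil, limma gave 43 higher and 47 lower without female methyltestosterone, 147 and 93 without male methyltestosterone, and 107 and 82 with all columns thinned to the lowest total. In the same order of comparisons limma with median-of-ratios scaling gave 327 higher and 276 lower, 283 and 251, and 349 and 505. Without the untreated female column limma gave 471 and 199, 82 and 42, and 273 and 588, and DESeq2 on the same 7 columns, where tool and scaling both differ, gave 226 and 348, 152 and 64, and 421 and 426. HIC1 (ENSGALG00000026718), a transcriptional repressor, was at 337 to 738 RPM in the 4 untreated and methyltestosterone columns and 2.03 to 22.2 in the other 4. RPL36 (ENSGALG00000000474), a ribosomal protein gene, was at 201 to 644 and 8598 to 12722 in the same order, RPS27A at 27.1 to 93.7 and 1565 to 2906, and the metalloproteinase inhibitor TIMP2 (ENSGALG00000027070) at 2.17 to 3.45 and 98.4 to 181. By a rule of at least 8-fold between all columns of the sets, after adding 2 RPM, 7 genes were higher in oil and tributyltin and 11 in untreated and methyltestosterone. The median log2 change over all genes was 0.36 for methyltestosterone against oil, -0.28 for oil against untreated and -0.28 for tributyltin against methyltestosterone. Median-of-ratios scaling brought these to 0.19, -0.21 and -0.16, so a change under about this size is not separate from the scaling.

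Against oil, several gonadal genes had higher values after methyltestosterone. SOX9 rose by 2.92 on the log2 scale (SE 0.73, limma adjusted p = 0.0394) and FOXL2 by 4.55 (SE 0.83, 0.0142 by limma), but in untreated gonads FOXL2 was at 126 in females and 25.1 in males, against 117 and 18.4 after methyltestosterone, and SOX9 at 30.8 and 273, against 13.6 and 322. Of 15 testis and Sertoli genes 3 rose (SOX9, CLDN11 and EMX2), or 4 adjusted over the list alone (camera adjusted p = 0.0853). Of 15 cholesterol genes 5 rose, also adjusted over the list alone, among them PMVK (1.73), SC4MOL (1.34) and FDFT1 (1.27), with a camera adjusted p of 0.196. In the heat shock and unfolded protein list XBP1 (-1.72), MANF (-1.65) and HSP70 (-2.70) were among 4 that fell and DNAJC3 rose, or 4 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.0853). PDK4 rose by 3.63 and the lipoprotein receptor SCARB1 by 3.46. AMH (1.43), STAR (-1.80) and DMRT1 (2.72) did not pass, with limma adjusted p of 0.0877, 0.100 and 0.116. The ribosomal list was the only one called, with 15 of 63 members lower and 2 higher (22 and 3 adjusted over the list alone) and a median of -0.29 (camera adjusted p = 6.70e-08, and adjusted p = 0.341 with an estimated correlation). With oil and untreated together as the control limma called 0 genes, and 721 had an unadjusted p under 0.05. That fit leaves the difference between oil and untreated in the residual spread, which lowers the count whatever methyltestosterone did. The 0 therefore does not show that the difference after methyltestosterone was absent.

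Oil against untreated compares sesame oil with no substance, across the sets, and steroid genes were among those that differed. STAR rose by 3.88 (SE 0.63, limma adjusted p = 0.00813), from 13.0 and 1.02 RPM in untreated females and males to 133 and 44.7 after oil, and LHCGR by 2.57, while the lipoprotein receptor SCARB1 fell by 2.52 (limma adjusted p = 0.0459). Of 20 steroidogenesis genes 2 thus rose and 1 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.414). PDK4 fell by 3.79, FOXL2 by 4.81 and SOX9 by 3.37. The heat shock gene HSP70 rose by 2.80. Among markers of other tissues, CHGA, PNMT and TH of the adrenal list and SLC34A1 of the kidney list fell. The kidney list (1 of 15 lower, or 9 adjusted over the list alone, median -1.87) and the ribosomal list (10 of 63 higher and 3 lower, or 20 and 10 adjusted over the list alone, median 0.40) had a camera adjusted p of 0.00234 and 7.08e-05. Each had adjusted p = 0.622 with an estimated correlation. Without the untreated female column, where gut markers were high, 124 genes were called, and without the untreated male column 248.

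Between the substances, tributyltin columns had lower AMH (log2 -1.72, SE 0.47, limma adjusted p = 0.0451) and FOXL2 (-5.58, SE 0.83, 0.00373 by limma) than methyltestosterone columns. Of 15 testis and Sertoli genes 3 were lower (EMX2, CLDN11 and AMH) and none higher, or 7 lower adjusted over the list alone (camera adjusted p = 0.0296, and adjusted p = 0.541 with an estimated correlation). Of 15 cholesterol genes 4 were lower (MVD, PMVK and FDFT1 among them) and 1 higher, also adjusted over the list alone, and 4 of 27 heat shock and unfolded protein genes were higher (XBP1, HERPUD1, MANF and HSP70) and 1 lower (6 and 3 adjusted over the list alone). Camera adjusted p was 0.256 for each. The ribosomal list had 15 of 63 higher and 3 lower, or 22 and 5 adjusted over the list alone (camera adjusted p = 9.43e-06, and adjusted p = 0.524 with an estimated correlation). The doses differed, and each substance had 1 pool per sex. Leaving out 1 column moved this count between 178 (without female methyltestosterone) and 1608 (without male oil).

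**Figure D3:**
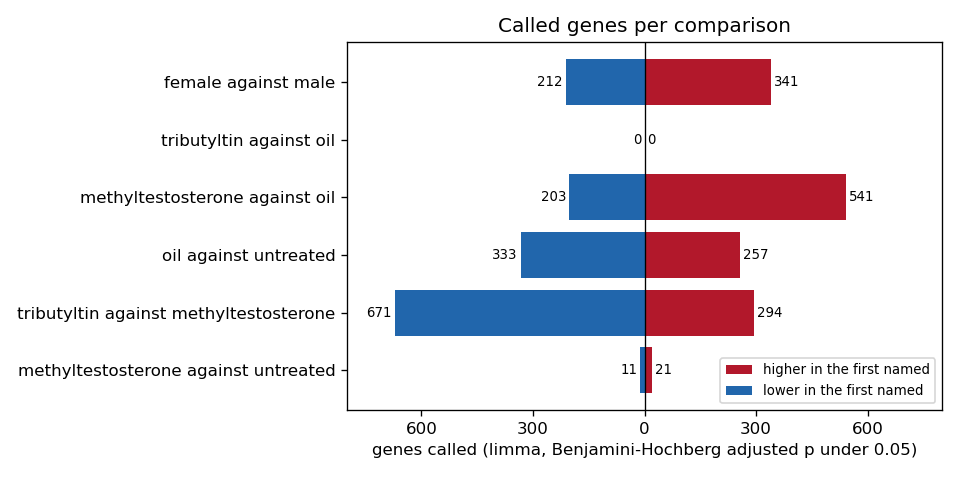
Number of genes called in limma at an adjusted p under 0.05 in each comparison, with those higher in the first named group to the right in red and those lower to the left in blue. Comparisons within a set of columns call 0 (tributyltin against oil) and 32 (methyltestosterone against untreated), those across sets 590 to 965, and the sex difference 553. The small count of 32 depends on the spread shared over all columns. With columns of only the compared substances limma called 0 and 1096 within the sets, in the same order, and 794 to 1461 across them.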

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

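For the genes below, the mixing test was fixed before its result was seen, and the reading that methyltestosterone acted was weighed after. In the methyltestosterone female column AMH was 4.56 times its untreated female value (6774 and 1486 RPM), and DMRT1 was at 31.1 and 9.56. Male gonads in that pool could give this, but over 140 genes higher in males the column lay a median of 1.97% of the way to the methyltestosterone male (quartiles -12.4 and 19.8), against 56.6% for AMH and 54.5% for DMRT1. Of the 140 genes 10 lay at or above AMH, which argues against mixing. An androgen that raises AMH and DMRT1 without SOX9 (13.6 and 30.8) may be at work, yet the ratio of 4.56 rests on 1 column and the oil control lies in the other set, so this stays open.

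Several genes moved in opposite ways in females and males, and these differences were not tested, because each sex and substance was 1 column. From untreated to methyltestosterone DMRT1 had a log2 change of 1.60 in females and -0.42 in males, and SOX9 one of -1.12 and 0.24. CYP17A1 had -0.21 and 0.58 from oil to methyltestosterone and 0.28 and -0.35 from untreated to oil. BTF3 had a copy on Z that was lower in females (log2 -1.26) and a copy on an unplaced scaffold that was higher (6.04). Tags of W genes in untreated and methyltestosterone males, at 11.4% and 14.4% of the female sums, had no counterpart in tributyltin males at 0, and the cause was not tested.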

How the results depend on the processing

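The choices of transformation, filter, model and lists and the rule for named genes were made before the data were examined, and genes outside that rule are given as such. The edgeR fit with TMM, the mean of at least 20 RPM, thinning, the sex difference within each set, the gut markers and the comparison of methyltestosterone with untreated were chosen after seeing the data. Reported counts were 553 genes by sex, 0 for tributyltin against oil, 744 for methyltestosterone against oil, 590 for oil against untreated, 965 for tributyltin against methyltestosterone and 32 for methyltestosterone against untreated. No paired analysis was possible because the columns carry no replicate numbers, other than the comparison of the sexes within each substance that the model makes. Left or right gonads alone, single tags, a block for the pool and a count test within 1 sex were not run, because sides were joined and each sex and substance was 1 column.

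Without the filter the counts were 193 by sex, 151 for methyltestosterone against oil, 203 for oil against untreated, 530 for tributyltin against methyltestosterone and 0 for methyltestosterone against untreated, and the Z median moved from -0.55 to -0.33. A pseudocount of 0.5 gave 19 for methyltestosterone against untreated. A pseudocount of 5 gave 60 there, 1 gene for tributyltin against oil, and a Z median of -0.37. With a mean of at least 20 RPM the first of these was 80 and the second 1. DESeq2 called 346 by sex, 2 for tributyltin against oil, 216 for oil against untreated and 49 for methyltestosterone against untreated. edgeR called 5 genes for tributyltin against oil with TMM, median-of-ratios or total scaling. In the same order it called 351, 345 and 352 for oil against untreated and 93, 97 and 87 for methyltestosterone against untreated. Thinning gave 286 by sex, 189 for methyltestosterone against oil, 237 for oil against untreated, 435 for tributyltin against methyltestosterone and 3 for methyltestosterone against untreated. The sex count was 1026 in the untreated and methyltestosterone columns alone and 27 in the oil and tributyltin columns alone. With columns of only the compared substances the counts were 1153 for oil against untreated, 1461 for tributyltin against methyltestosterone and 1096 for methyltestosterone against untreated. With oil and untreated as a joint control methyltestosterone had 0, in a fit whose residual spread holds the difference between oil and untreated. With an estimated correlation the called lists went from 15 by sex, 1, 2, 2 and 7 in the later comparisons to 0 in each. The fewer degrees of freedom of that form lower the calls as well, so this loss is not a measure of correlation alone.

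Leaving out single columns gave 216 (female tributyltin) to 449 (male methyltestosterone) by sex, with 228 without male tributyltin. For tributyltin against oil the range was 0 (male tributyltin) to 49 (male oil), with 2 or 3 genes when a single untreated, methyltestosterone or female oil column was left out. For methyltestosterone against oil it was 90 (female methyltestosterone) to 1178 (male oil), with 377 without female oil and 240 without male methyltestosterone. For oil against untreated it was 124 (female untreated) to 1045 (male oil), with 248 without male untreated. For tributyltin against methyltestosterone it was 178 (female methyltestosterone) to 1608 (male oil), with 1594 without female oil, 541 without male methyltestosterone, and 384 and 207 without male and female tributyltin. For methyltestosterone against untreated it was 0 (either tributyltin) to 48 (female oil), with 20 without female untreated and 14 without female methyltestosterone. The Z median stayed at -0.56 to -0.47. The cause of these shifts was not tested. Over 242 named genes that were called, 3637 of 4588 alternative values were the same, 951 were weaker and 0 were reversed. Over 58 named genes that were not called, 954 of 1117 values were the same and 83 were stronger, that is called in the same direction. A further 80 changed direction without a call, and 0 changed direction with a call. The lack of a call thus depended on the choices for part of these genes, and so did the direction. For methyltestosterone against untreated, 21 genes were higher and 11 lower as reported, 20 and 19 with median-of-ratios scaling, 15 and 5 in limma without female untreated, and on the same 7 columns 25 and 24 with DESeq2 and 43 and 50 with edgeR and TMM.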

Other observations

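The sex difference was measured in substances that had no part in calling the genes. A filter for a mean of at least 20 RPM did use all 8 columns, the held-out ones included. Genes called in the other 3 substances kept 93.6% (male-high) and 112% (female-high) of their median difference in oil, 78.7% and 84.3% in untreated, 106% and 102% in tributyltin, and 76.5% and 70.8% in methyltestosterone gonads.

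The gut tissue and depth tests were written before their results were seen, and the counting intervals of the gut markers, the test of absence in both sexes, the ribosomal spread and the sesame oil reading came after. In the untreated female column 17 of 22 gut markers not seen before were higher than in any other column, against 2.75 if columns were alike and markers independent, which markers of 1 tissue in 1 pool are not. Of the 17, 6 rested on fewer than 5 tags and 4 (VIL1 and FABP2 among them) had a counting interval above those of all other columns, while KRT19 was at 316 there and at 870.4 and 877 in oil and tributyltin females. Intestine carried into that pool could explain genes such as PLA2G2E (786 and 0 after methyltestosterone) and TACSTD1 (256 and 7.29). The lack of any substance is argued against as a cause in both sexes, because untreated males held a median of 2.04% of the female value over markers highest in that column and 1.80% over the 22 not chosen by their values, though DPP4 was at 126%, CLDN3 at 58.9% and KRT19 at 32.7%. Among markers highest in that column FABP6 was at 1012, TSPAN8 at 294 and LGALS2 at 199, but FABP6 was also at 217 to 268 in males, and an effect on females alone stays open.

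Untreated and methyltestosterone columns differed from oil and tributyltin columns in genes such as RPL36 and TIMP2, with 18 genes parting the sets by over 8-fold. Depth is argued against, because after thinning to 314810 tags the median change of the 590 genes that differed between oil and untreated was 98.7% of its full size, all in the same direction, although 234 of them passed in the thinned columns. A difference in tag assignment or library preparation might scatter ribosomal genes, whose spread across sets was at least 1.18 times that within a set (1.43 to 1.59 across, 0.616 and 1.21 within), a ratio that does not decide. Sesame oil itself could part the same 18 genes if both oil and tributyltin gonads received it and methyltestosterone gonads did not. The labels do not name the vehicle of either substance, so oil and preparation stay unresolved, and comparisons that cross the sets carry both.

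The split of the 8 columns by sex was compared with the other splits into 4 and 4, a test fixed before its result was seen, and 32 of 35 could be fitted. The real split called 553 genes, 1 split reached that count, and the highest other count was 0. Only 8 splits, the real one included, are balanced over the substances as sex is, which is too few for a share under 0.05. Every other split also leaves the sex difference in the residual spread, which lowers its count by construction.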
